A study of Mus musculus with 3 samples.

How the data were processed

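The deposited tables hold raw UMI counts per gene and cell barcode, with no normalization by the authors, in 1 table for each of the 3 libraries. Cells were stained and sorted for CD11b and CD45 after enzymatic digestion and density centrifugation, and libraries were made with the 10x Genomics droplet 3' kit, per the labels' protocols. Cell Ranger 3.0, Seurat 2.2 and the build mm10 are named in the submitters' processing notes. Filters used by the authors are not given in the sources used here. The tables held no barcode with fewer than 200 genes, and the highest mitochondrial share was 9.66%. Nearly all listed genes had UMIs in at least 5 cells of the library: 2, 13 and 17 listed genes of WT 1, WT 2 and the deficient library had fewer. A gene that a table does not list is therefore below a limit of about 5 cells, not measured as 0. The tables list 13770, 13695 and 12077 genes.

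Cells with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet, run per library, called 29 of 11264 cells (0.257%) as doublets. WT 1 and WT 2 had 0 and 1 calls and the deficient library 28 of 2257 cells, so removal was unequal between the genotypes. Over all cells the caller is taken not to have worked, so doublets can remain. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen without MHC class II list members and sex-linked genes, and 30 principal components entered Leiden clustering at resolution 1 (scanpy 1.11.5, leidenalg 0.10.2). Clusters were named from marker lists fixed beforehand, with at least 3 markers each in 10% of cells and a summed marker level at least 4-fold that of the other cells, and otherwise as microglia where the microglial marker share reached 0.5 of the median cell's; these thresholds were set with the data in hand. Leading genes were those with the highest fold among genes in 15% of cells. Microglia were re-clustered at resolution 0.5. A cluster with more markers of another class than of its own among its 10 leading genes against all other cells stayed unnamed, as did a cluster with a median UMI count far under that of its library.

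The clusters this naming rule left out of the microglia were then seen, and a second version of it was written that takes the leading genes of a microglia cluster against the cells of other classes only. The second version was for a time used in place of the first. The first was put back as the main rule because it had been set before its outcome was known, and the second is given as an alternative.

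UMIs of microglia-like cells were summed per library, since cells are not replicates. Genes listed in all 3 tables (11979) that passed filterByExpr were tested with edgeR 4.0.16 (quasi-likelihood, TMM normalisation, deficient minus WT) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The design text names 2 WT mice and 1 deficient mouse, and p-values rest on the spread of this WT pair alone. Fold changes without a WT library have no test. They are log2 ratios of CPM plus 1, while the main values are edgeR fold changes without that addition. A value without a WT library can therefore differ from the main value through the measure as well, most for genes with few UMIs. Gene lists, fixed before the data were examined with the tests, markers and the rule for named genes, were tested with camera (preset correlation 0.01, and estimated) and fry in limma 3.58.1. The estimated correlation rests on 1 residual degree of freedom, and so does fry. Members were counted over all genes and adjusted over the list alone. Named genes were every MHC class II list member, the 10 largest log2 fold changes in each direction past the threshold with a mean of at least 20 CPM and the deficient value outside the WT range (genes with Gm numbers, Rik genes and sex-linked genes left out), and of each list the 3 members with the highest mean CPM and the 1 with the largest fold. Cd3e and Cd4 were named for T cells. Rnaset2a, Tagap, Top2a, Mki67 and Cd3d were named after their values were seen. Some genes that the rule takes are not reported here.

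The edgeR step was tested on simulated counts with the real means and library totals of this comparison. Over 5 simulations of 11695 genes, 99.6% and 100% of genes changed by -2 and 2 on the log2 scale were called, and 86.4% and 95.2% of those changed by -1 and 1, with 4.60% of calls false. Changed genes were drawn from those with at least 5 CPM in WT, and every library was given the dispersion of the WT pair. The simulations thus took for granted that the lone deficient library varies like WT, and cannot test it. Shares have exact Clopper-Pearson 95% intervals, which cover counting error only. Positions are from GENCODE release 21 for mouse on the same build, in which 98.7% of the 14221 gene symbols had 1 position. Alternatives covered normalisation, count and cell filters, doublets, depth, cell sets, tools (DESeq2 1.42.0, limma voom), clustering, and each WT library left out.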

Results

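Single-cell RNA libraries were made from CD11b+ CD45+ cells sorted from adult mouse brain, a gate that takes microglia, the resident macrophages of the brain, with other myeloid cells. The samples comprised 2 wild type (WT) libraries and 1 library from a mouse deficient in MHC class II, the peptide-presenting molecules that CD4 T cells need for their development and recognise on other cells. The comparison asked how microglia differ in an animal with very few CD4 T cells. The tables held 4589 and 4815 barcodes for WT 1 and WT 2 and 2278 for the deficient library, with 16230216, 17293844 and 6616662 unique molecular identifiers (UMIs). After filtering, 4340, 4666 and 2229 cells remained, with median depths of 3384.5, 3338 and 2816 UMIs. The deficient group had 1 library, so no spread between deficient animals was measured.

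The MHC class II genes were examined first. The table of the deficient library did not list H2-Aa, H2-Ab1 or H2-Eb1, the classical class II chains, and the tables list almost no gene seen in fewer than 5 cells. In all retained cells, H2-Ab1 stood at 235.4 CPM (UMIs scaled to a common total) in WT 1 and 258.02 CPM in WT 2. H2-Aa stood at 186.03 and 204.5 CPM, and H2-Eb1 at 161.6 and 170.4 CPM. The listing limit is in cells, and positive cells can hold many UMIs (H2-Aa had 2824 UMIs in 52 border-associated macrophage-like cells of WT 1), so no ceiling in CPM is given for the deficient library. Most UMIs of these genes came from border-associated macrophage-like cells, with 3392 of 3802 H2-Ab1 UMIs in WT 1 and 3627 of 4448 in WT 2. H2-Ab1 UMIs were found in 6.55% and 6.69% of WT microglia-like cells and in 5.08% and 4.90% of WT neutrophil-like cells, with median depths of 3404 and 3333 against 3055 and 3392 UMIs. After thinning each cell to 1000 UMIs, the shares were 1.964% and 2.001% against 0.707% and 0.763%. No fold was drawn for microglia-like cells, since free RNA can give such shares. Cd74, the invariant chain that escorts class II molecules, stood at 632.3 CPM in WT 1, 710.9 CPM in WT 2 and 442.7 CPM in the deficient library over all cells. In border-associated macrophage-like cells, which held most Cd74 UMIs, it stood at 19855 CPM (76 cells), 20028 CPM (68 cells) and 36580 CPM (15 cells) in WT 1, WT 2 and the deficient library, so there it was highest in the deficient library. The listing of these genes matched the genotype labels. Among the 6 class II list members that could be tested in microglia-like cells, H2-Oa rose by a log2 fold change of 0.45 (SE 0.10, adjusted p = 0.00615, edgeR), a call that DESeq2 did not make (adjusted p = 0.299). Cd74 stood at a mean of 44.5 TMM-normalised CPM in WT microglia-like cells and 43.1 CPM in those of the deficient library, a difference that did not pass (adjusted p = 0.883).

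Most cells of every library were microglia-like. They made up 83.4% of cells in WT 1 (exact Clopper-Pearson 95% interval 82.3 to 84.5), 87.8% in WT 2 (86.9 to 88.8) and 93.0% in the deficient library (91.9 to 94.03). Neutrophil-like cells made up 6.80% of WT 1 (6.07 to 7.59), 3.06% of WT 2 (2.59 to 3.60) and 0.852% of the deficient library (0.514 to 1.33). Border-associated macrophage-like cells made up 1.75% (1.38 to 2.19), 1.46% (1.13 to 1.84) and 0.673% (0.377 to 1.11) of WT 1, WT 2 and the deficient library. At a clustering resolution of 0.5, which named no monocyte class, they made up 2.88%, 2.29% and 1.53%. Classical monocyte-like cells made up 0.991% (0.718 to 1.33), 0.643% (0.434 to 0.917) and 0.179% (0.0489 to 0.459). With a strict cell filter (at least 1000 UMIs and 500 genes, at most 5% mitochondrial UMIs) they made up 1.23%, 0.854% and 0.820%, with no non-classical class named, so the deficient share then lay close to that of WT 2. The same filter gave 0.547% neutrophil-like cells in the deficient library. Non-classical monocyte-like cells made up 0.230% (0.111 to 0.423), 0.257% (0.133 to 0.449) and 0.673% (0.377 to 1.11). The intervals cover counting error only, and the CD11b+ CD45+ gate can set these shares. The share of neutrophil-like cells differed between the 2 WT libraries themselves, and an exact permutation test of 2 libraries against 1 cannot give a p under 1 in 3, so none was run. No class other than microglia had 50 cells in every library, so genes were tested in microglia only. Clusters with microglial markers were left out of the class where their leading genes held a marker of another class. The cluster led by interferon-induced genes, with the plasmacytoid dendritic cell marker Bst2 among its leading genes, held 250, 241 and 81 cells of WT 1, WT 2 and the deficient library. The cluster led by Lpl and Cst7, with Itgax among its leading genes, held 36, 66 and 22 cells. A cluster with a low UMI count held 10, 8 and 0 cells. Within the class, most deficient cells lay in cluster 3 (1356 cells), led by Ccr6 and Tagap1, and cluster 8 (285 cells), while clusters 0, 1 and 2 held 1300, 636 and 650 cells of WT 1 and 759, 1357 and 954 of WT 2, against 17, 14 and 94 of the deficient library.

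No cluster was T cell-like. Cd3e, a chain of the T cell receptor complex, and Cd4 were listed in none of the 3 tables. Cells with a UMI of Cd3d, another chain of that complex, made up 0.599% of WT 1 (exact Clopper-Pearson 95% interval 0.392 to 0.877) and 0.386% of WT 2 (0.229 to 0.609). Of these 26 and 18 cells, 18 and 10 were neutrophil-like, and in microglia-like cells, which should lack the gene, the share was 0.193% (0.0778 to 0.398) and 0.122% (0.0396 to 0.285). Median depth was 3055 and 3392 UMIs in neutrophil-like cells and 3404 and 3333 in microglia-like cells. After thinning each cell to 1000 UMIs, the share over all cells was 0.117% and 0.0654%. The table of the deficient library listed no Cd3 gene, which places such cells under the listing minimum of 5 cells, or 0.224% of its cells. The sort for CD11b, a myeloid integrin, would leave most T cells out, so these values do not measure the T cells of the brain.

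Microglia-like cells of the deficient library differed from WT in 980 of 11828 tested genes, 202 higher and 778 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among genes with a mean of at least 20 CPM, the largest higher were Ccr6, a chemokine receptor, and Tagap1, a putative GTPase-activating protein. Ccr6 stood at 1.53 and 1.78 CPM in the WT libraries and 152.5 CPM in the deficient library, a log2 fold change of 6.51 (SE 0.14, adjusted p = 5.97e-14). Tagap1 stood at 8.35 and 8.70 CPM against 117.5 CPM, a log2 fold change of 3.78 (SE 0.11, adjusted p = 6.55e-12). The other higher genes with the largest folds were Gdf15, a stress-induced cytokine (log2 fold change 2.02, and 3.15 without WT 1 or 1.23 without WT 2), Ddit4, an inhibitor of mTOR signalling (1.87), Oser1 (1.45), Ppcs (1.17), the interferon-induced Ifi27l2a (1.16), Snhg20 (1.11), Gstp1, a glutathione transferase (1.07), and Dynlt1c (0.97). Gdf15 was not called by DESeq2 (adjusted p = 0.9997) or without proliferation or immediate early clusters (adjusted p = 0.638), and Ifi27l2a stood at 0.056 over all retained cells (adjusted p = 0.904). On the mm10 build, Ccr6 lies at chromosome 17, 8236043 to 8257141, and Tagap1 at 6955011 to 6961156 of the same chromosome. The fold of Tagap1 is uncertain because of its similar copy Tagap, described with the lower genes below.

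Among the lower genes, Klf2, a transcription factor of the Krüppel-like family, stood at 1604 and 1114 CPM in WT against 23.2 CPM, a log2 fold change of -5.87 (SE 0.24, adjusted p = 2.03e-10). Jund, a subunit of the AP-1 transcription factor, stood at 1663 and 1079 CPM against 76.1 CPM, a log2 fold change of -4.17 (SE 0.23). Cebpa, a transcription factor of the myeloid lineage, had a log2 fold change of -4.09 (SE 0.16). Dapk3, a protein kinase, had a log2 fold change of -5.90 (SE 0.27), Kcnk12, a potassium channel subunit, -4.81 (SE 0.20), and Rnaset2b, a ribonuclease, -4.37 (SE 0.14). Rnaset2b is nearly identical to its neighbour Rnaset2a, which rose by 0.80, and Tagap1 resembles Tagap, which fell by 2.66. UMIs can thus be split between the copies. Rnaset2a stood at a mean of 296.4 CPM in WT and 517.5 CPM in the deficient library, and Rnaset2b at 250.01 and 12.04 CPM. Tagap stood at 123.99 and 19.56 CPM, and Tagap1 at 8.53 and 117.5 CPM. In each pair the rise of the higher copy in CPM was close to the fall of the lower copy. The folds of single copies are therefore uncertain and do not show a change of the pair, whose summed counts were not tested. The remaining 4 of the 10 largest under the same limit were Camp (-5.22), Ngp (-4.85), S100a9 (-4.15) and Retnlg (-4.06), which are neutrophil granule or neutrophil-secreted products. By ratios of CPM plus 1, Retnlg stood at -2.63 without WT 1 and -4.24 without WT 2. Retnlg was not called by limma voom (adjusted p = 0.19998). These 4 genes moved with the share of neutrophil-like cells, which was 6.80% and 3.06% in WT and 0.852% in the deficient library.

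**Figure D1:**
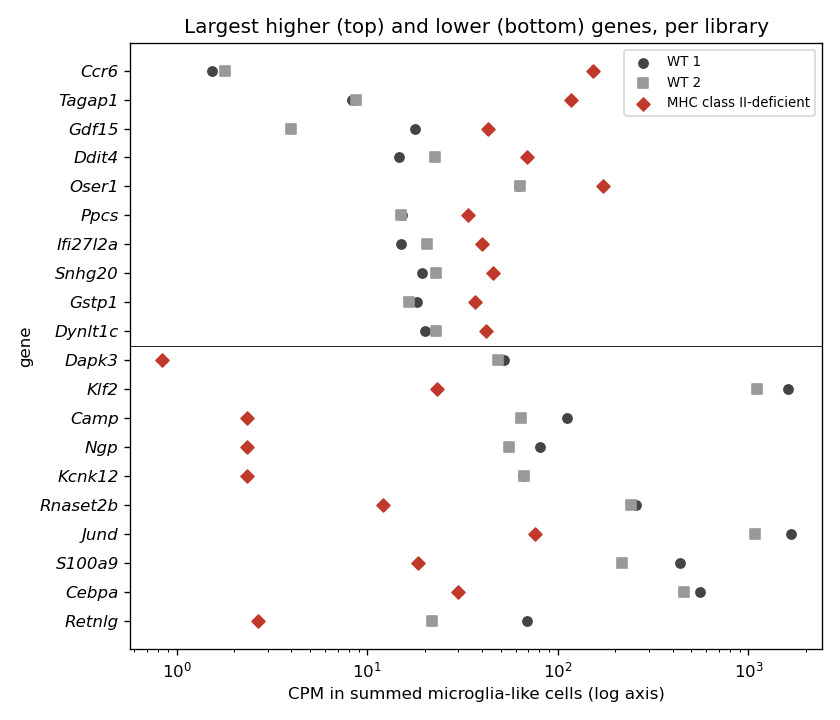
CPM, on a log axis, of the 10 higher and 10 lower genes past the threshold with the largest log2 fold changes among genes with a mean of at least 20 CPM (Gm-numbered, Rik and sex-linked genes left out), in the summed microglia-like cells of WT 1 (circles), WT 2 (squares) and the MHC class II-deficient library (diamonds), with no error bars because each point is 1 library. Ccr6 lies at 152.5 CPM in the deficient library and at 1.53 and 1.78 CPM in WT, and Klf2 at 23.2 CPM against 1604 and 1114 CPM.

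The difference between the deficient library and WT was wider than that between the 2 WT libraries. The log2 ratio of CPM had an SD over genes of 0.44 for the deficient library against the WT mean, and 0.21 for WT 1 against WT 2, with a pseudocount of 1 CPM. Ratios over 1 in size were found for 3.34% and 0.245% of genes, and the median size was 0.163 and 0.104. The summed microglia held 6004273 UMIs in the deficient library against 12978322 and 14652724 in WT 1 and WT 2. These sums were not thinned, so counting noise can add to the wider spread. The same fit with WT 1 or WT 2 as the single library called 0 genes each, and 980 with the deficient library, with 116 and 45 genes at an unadjusted p under 0.05 against 2274 for the deficient library (edgeR). Those fits pair the deficient library with a WT library, which raises the dispersion to 0.0360 and 0.0439 from 0.00441, so their counts do not measure how alike the WT libraries are. With 3 choices the share cannot fall under 0.05. The test has 1 residual degree of freedom, from the WT pair, and assumes that the lone library varies like WT. With DESeq2, 56 genes were higher and 418 lower.

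**Figure D2:**
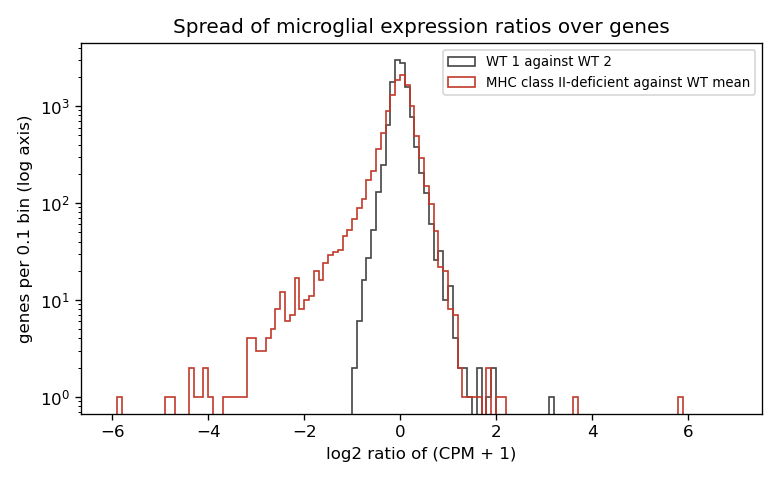
Number of genes (log axis) by log2 ratio of CPM plus 1 in microglia-like cells, for WT 1 against WT 2 (grey) and the deficient library against the WT mean (red). The deficient library has the wider spread, an SD of 0.44 against 0.21, with a long tail of lower genes.

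Genes of the immediate early and dissociation stress list, which respond within minutes to stimuli and to tissue digestion, fell in 18 of 33 measured members. Of the others 0 rose and 15 did not pass, with a median log2 fold change of -0.87 over the list (camera with preset correlation, adjusted p = 1.58e-19, and adjusted p = 0.846 with an estimated correlation). Adjusted over the list alone, 25 fell and 1 rose. With the strict cell filter, 0 rose adjusted over the list alone. That setting also left unnamed a cluster with 653, 1236 and 34 cells of WT 1, WT 2 and the deficient library, so its list counts below are not those of the filter alone. The strict filter with the alternative naming (leading genes of a cluster taken against the cells of other classes), a setting chosen after the data were seen, kept that cluster among the microglia. Klf2, Jund and Jun (log2 fold change -0.97) were among those that fell, while Junb (-0.55, adjusted p = 0.0910) did not pass and stood at -0.22 without WT 1 and -0.81 without WT 2. Jun was not called by DESeq2 (adjusted p = 0.216). The alternative without proliferation or immediate early clusters kept 1804 of 3620 microglia-like cells of WT 1 and 2960 of 4098 of WT 2. It kept 1720 of 2073 in the deficient library. The share of cells in such clusters thus differed between the WT libraries themselves as well.

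A minority of interferon-induced genes rose. Of 31 measured members of the type I interferon list, 6 rose, 0 fell and 25 did not pass, with a median log2 fold change of 0.28 (camera adjusted p = 3.15e-06, and adjusted p = 0.846 with an estimated correlation), and 9 rose adjusted over the list alone. The interferon-led cluster, with 250, 241 and 81 cells of WT 1, WT 2 and the deficient library, is not among these cells. Ifi27l2a and Bst2 (log2 fold change 0.34, adjusted p = 0.0306) rose, and Trim30a (0.28, adjusted p = 0.0847) did not pass. Bst2 was not called by DESeq2 (adjusted p = 0.287), by limma voom (0.0541) or without proliferation or immediate early clusters (0.107). Of 20 measured interferon-gamma list members, 2 rose, 0 fell and 18 did not pass (camera adjusted p = 0.0199, and adjusted p = 0.846 with an estimated correlation). The guanylate-binding protein Gbp7 rose by a log2 fold change of 0.71. Adjusted over the list alone, 4 rose and 2 fell. With the strict filter 3 rose and 2 fell over all genes, and the list did not pass (camera adjusted p = 0.104), while with the alternative naming as well it passed (camera adjusted p = 0.0163).

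In the list of TGF-beta signalling, a pathway that maintains adult microglia, 6 of 21 measured members fell, 0 rose and 15 did not pass (camera adjusted p = 0.00667, and adjusted p = 0.846 with an estimated correlation), and 8 fell adjusted over the list alone. Its median log2 fold change of -0.18 was -0.084 without WT 1 and -0.27 with the strict filter. Smad7, an inhibitor of the pathway that it also induces, fell by 2.15 on the log2 scale, Itgb5 by 0.66 and Tgfb1 by 0.43, while Tgfbr1 stood at 871.1 CPM in WT and 926.97 CPM in the deficient library and did not pass. Itgb5 was not called by DESeq2 (adjusted p = 0.132), nor Tgfb1 over all retained cells (adjusted p = 0.0745). Since the list holds inhibitors such as Smad7, lower members do not show a weaker pathway. At a re-clustering resolution of 1, Smad7 shared the leading genes of a cluster with Hspa1a and Hspa1b of the dissociation stress list. That cluster held 1210, 707 and 14 cells of WT 1, WT 2 and the deficient library. Of 24 measured cell cycle genes, 5 fell, 0 rose and 19 did not pass (camera adjusted p = 0.00531, and adjusted p = 0.846 with an estimated correlation), and 5 fell adjusted over the list alone. Its median of -0.43 was -0.26 without WT 2, the latter by ratios of CPM plus 1. Pcna fell by 0.93 and Hmgb2 by 0.51 on the log2 scale, and Hmgb2 was not called without proliferation or immediate early clusters (adjusted p = 0.524) or by DESeq2 (0.0867). The cell cycle counts leave out members that the deficient library does not list, among them Top2a and Mki67. Of 30 measured inflammatory cytokine and NF-kB target genes, 7 fell, 1 rose and 22 did not pass (camera adjusted p = 0.0199, and adjusted p = 0.846 with an estimated correlation), and 9 fell and 1 rose adjusted over the list alone. Cebpb fell by 2.98 on the log2 scale, and Ccl4 (-0.27, 0.42 without WT 1), Ccl3 (-0.56, 0.23 without WT 1) and Nfkbia (-0.29, 0.23 without WT 1) did not pass. The median of the list was -0.18, 0.039 without WT 1 and -0.28 without WT 2. Of the 30 genes 15 fell with the strict filter, 17 adjusted over the list alone, with a median of -0.40, and 6 fell with the alternative naming as well.

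Of 78 measured cytosolic ribosomal protein genes, 5 rose, 0 fell and 73 did not pass, with a median log2 fold change of 0.24 (camera adjusted p = 7.70e-19, and adjusted p = 0.846 with an estimated correlation), and 5 rose adjusted over the list alone. Under the strict filter 43 of them rose, and 65 adjusted over the list alone, but 4 by either count with the alternative naming as well. Rpl35 rose by 0.84 on the log2 scale, and Rps29 and Rplp1 did not pass. Of 13 mitochondrially encoded genes, 1 rose, mt-Cytb (0.45, adjusted p = 0.0196), and 6 rose adjusted over the list alone (camera adjusted p = 2.84e-05, and adjusted p = 0.846 with an estimated correlation). Over all retained cells mt-Cytb was not called (adjusted p = 0.0826), and with the strict filter 8 of the 13 rose, but 1 with the alternative naming as well. Of 82 nuclear-encoded oxidative phosphorylation genes, 0 passed over all genes or adjusted over the list alone, with camera adjusted p = 0.00157, and adjusted p = 0.846 with an estimated correlation. The list had a median log2 fold change of 0.10, or 0.049 without WT 1 and 0.16 without WT 2. Of the 82 genes 11 rose with the strict filter, and 12 adjusted over the list alone, with a median of 0.16, but 0 with the alternative naming as well. The MHC class II list had camera adjusted p = 0.0291 in the higher direction over its 6 tested members, and adjusted p = 0.846 with an estimated correlation. It had 3 members higher adjusted over the list alone, and left out the unlisted H2-Aa, H2-Ab1 and H2-Eb1. Its median of 0.21 was 0.094 without WT 1 and 0.32 without WT 2. With the strict filter 3 rose and 1 fell, and the list did not pass (camera adjusted p = 0.155, and 0.121 with the alternative naming as well).

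Lists of microglial identity and maturation did not pass as lists in the main setting. Of 30 measured homeostatic microglia genes, 0 passed over all genes or adjusted over the list alone, with a median log2 fold change of 0.046 (camera adjusted p = 0.168), or 0.0014 without WT 1 and 0.098 without WT 2, and with the strict filter 3 rose, but 0 with the alternative naming as well. P2ry6, a nucleotide receptor, had a log2 fold change of 0.33 (adjusted p = 0.0916). Of 14 measured adult-stage genes, 2 fell, among them Jun (log2 fold change -0.97), and 0 rose (camera adjusted p = 0.168), with the same counts adjusted over the list alone. Its median of -0.053 was -0.086 without WT 1 and -0.029 without WT 2, and with the strict filter the list passed in the lower direction (camera adjusted p = 0.0374), but not with the alternative naming as well (0.195). Of 27 fetal and early postnatal genes, 3 rose and 3 fell (camera adjusted p = 0.749), and 5 rose and 5 fell adjusted over the list alone. Its camera direction was higher while its median (-0.051) and mean (-0.20) were below 0. By ratios of CPM plus 1 the median was -0.040 without WT 1 and 0.095 without WT 2, so its sign depended on the WT library used. Of these genes 6 rose and 5 fell with the strict filter, and 3 and 2 with the alternative naming as well. Ccr1, a chemokine receptor, rose by 0.78 on the log2 scale, and stood at 0.18 over all retained cells (adjusted p = 0.441); DESeq2 did not call it (adjusted p = 0.0976). Of 14 genes of axon-tract-associated postnatal microglia, 1 fell (camera adjusted p = 0.455), also adjusted over the list alone, and the median of -0.045 was 0.031 without WT 2, and 2 fell with the strict filter, but 1 with the alternative naming as well. Of 26 disease-associated genes, 2 rose and 4 fell (camera adjusted p = 0.748), also adjusted over the list alone, and Timp2 fell by 2.196 on the log2 scale. That list had a median of 0.011, a mean of -0.28 and a lower camera direction, and its median was 0.0015 without WT 1 and 0.031 without WT 2. With the strict filter 4 rose and 7 fell, with a median of -0.021, and 1 rose and 3 fell with the alternative naming as well.

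The remaining lists did not pass with camera either. Of 44 lysosome genes 2 fell, with Lamp1, a lysosomal membrane protein, at a log2 fold change of -3.08, and 1 fell adjusted over the list alone; its median (0.050) and camera direction lay above 0 and its mean (-0.054) below, with a median of 0.0025 without WT 1 and 0.085 without WT 2. Of 35 phagocytic receptor genes 4 fell, among them Siglece (-0.83), and 2 rose and 5 fell adjusted over the list alone, with a median of 0.095, a mean of -0.00088 and a higher camera direction. Siglece was not called by DESeq2 (adjusted p = 0.133), and with the strict filter 7 phagocytic receptor genes rose and 5 fell, but 0 and 4 with the alternative naming as well. Of 19 MHC class I pathway genes 2 fell, among them H2-T23 (-1.27), also adjusted over the list alone, and with the strict filter 1 rose and 3 fell. Of 32 cholesterol and lipid genes 1 fell, Fdps (-0.56), and 0 adjusted over the list alone. The Fdps call was lost in 6 alternatives, with adjusted p from 0.0520 to 0.721. Of 25 glycolysis and hypoxia genes 1 rose, Ddit4, also adjusted over the list alone, and the median of 0.0014 was -0.0094 without WT 1; with the strict filter 1 fell as well. Of 14 complement genes 0 passed by either count, with C1qa at 10379 CPM in WT and 12698 CPM in the deficient library, while with the strict filter 3 rose and 1 fell and the median of 0.10 was -0.017, and with the alternative naming as well 0 passed and the median was -0.020. Of 4 sex-linked genes 1 fell, Ddx3y (-0.48), and 2 fell adjusted over the list alone, with a median of -0.24 that was -0.13 without WT 2. Ddx3y was not called by DESeq2 (adjusted p = 0.180) or without proliferation or immediate early clusters (adjusted p = 0.134).

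Microglia-like cells of the genotypes lay mostly in different clusters, which were led by genes that differed between the genotypes, so cluster shares are not a result separate from those genes. After re-clustering, in the deficient library 83.98% of microglia-like cells (exact Clopper-Pearson 95% interval 82.3 to 85.5) lay in clusters that held under 5% of each WT library. That share was not stable. With the leading genes of a cluster taken against the cells of other classes, an alternative tried after the first result was seen, it was 13.6%, and 1.16% and 92.5% at re-clustering resolutions of 0.3 and 1.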

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

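The alternative naming of clusters and those for unlisted genes were chosen after seeing the data. With the alternative naming, 213 genes were higher and 796 lower, and 951 of the called genes were shared. Higher genes numbered 459 with the strict cell filter, 122 over all retained cells and 56 with DESeq2, which called 418 lower; the strict filter also left a large mostly WT cluster unnamed, and with the alternative naming as well 163 were higher, 730 lower and the MHC class II list had adjusted p = 0.121. All other settings stayed within 1.5 times. The share of deficient microglia in clusters nearly free of WT cells, 83.98% as reported, was 93.3% at a re-clustering resolution of 1, and with the alternative naming 13.6%, 1.16% at resolution 0.3 and 92.5% at resolution 1. With clusters drawn from WT cells alone it was 0, a value that this setting largely fixes. Only a small cluster led by Top2a and Mki67 held under 5% of each WT library, with 4 and 17 cells of WT 1 and WT 2. No deficient cell was assigned to it. The share as a summary was itself chosen after the clusters were seen, its cause was not tested, and it is not a stable value.

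With an estimated correlation every called list had adjusted p = 0.846. That setting and fry rest on 1 residual degree of freedom, so they can decide little for or against a list. With fry, adjusted p was 0.574 for MHC class II, 0.338 for both interferon lists, ribosomal and mitochondrially encoded genes, 0.473 for immediate early and cell cycle genes, 0.767 for NF-kB targets, 0.424 for TGF-beta and 0.703 for oxidative phosphorylation; MHC class I (0.338) and lysosome (0.685) changed direction. With the strict filter adjusted p was 0.155 for MHC class II, 0.104 for interferon-gamma, 0.0374 for adult-stage genes and 0.990 for MHC class I, which changed direction. Without WT replicate 1 the median of NF-kB targets was 0.0393, and -0.278 without WT replicate 2. Medians also changed sign for fetal (0.0953) and axon-tract genes (0.0311) without WT replicate 2 and for glycolysis (-0.00937) without WT replicate 1. Among named genes, none that passed changed sign. Without WT replicate 1, 0.42 was found for Ccl4, 0.23 for Ccl3 and Nfkbia, -0.0433 for H2-DMb1 and -0.0319 for Selplg; 8 others also changed sign without a WT replicate, to values within 0.1 of 0. Of those that did not pass, log2 fold changes became -0.0253 for Abca1, 0.13 for Cd74, -0.0142 for Ctsb and 0.029 for Eif2s3y without proliferation or immediate early clusters, -0.081 for Aldoa, -0.12 for H2-D1 and 0.026 for Irf8 over all cells, 0.060 for Apoe with the alternative naming and -0.021 for H2-D1 with doublets kept.

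Microglia were 96.5% (deficient) and 91.0% (WT mean) at resolution 0.5, 94.3% and 89.3% with doublets kept, 96.6% and 91.1% with the alternative naming, and 70.4% (WT mean) with the strict filter. Border-associated macrophages were 1.53% and 2.59% at resolution 0.5, where no monocyte class was named, and classical monocytes 0.820% of the deficient library with the strict filter, where no non-classical class was named. Over microglia only, Cd74 stood at 43.1, 45.9 and 42.97 CPM in WT 1, WT 2 and the deficient library, H2-Aa at 7.86 and 6.07, H2-Ab1 at 21.3 and 20.5 and H2-Eb1 at 9.63 and 5.19 CPM in WT. Over all retained cells, after thinning each cell to 1000 UMIs, Cd74 was seen in 4.70%, 4.88% and 3.99% of cells, H2-Aa in 1.81% and 1.72%, H2-Ab1 in 3.08% and 3.16% and H2-Eb1 in 1.78% and 1.46%. No paired analysis was possible because the deficient group has 1 library. Gene tests in other cell classes, and alternatives to them, were not run, since none had enough cells in every library.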

Other observations

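The tests of GC content, of an even spread of calls over the genome and of free neutrophil RNA were chosen only after related values were seen. Both WT tables list 1290 genes that the deficient table does not. With unlisted genes set to 4 UMIs, 245 genes were higher and 822 lower, and with them set to 0, 231 and 905, so what they add depends on the value set. Top2a and Mki67, which mark dividing cells, are among them, with 44 and 135 UMIs and 32 and 69 UMIs in microglia of WT 1 and WT 2. No fold is given, since the listing limit is in cells and a dividing cell can hold many of these UMIs.

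Lower genes outnumbered higher genes in deficient microglia by a ratio of 3.85. The size of this excess varied with the setting. Higher and lower genes numbered 459 and 1089 with the strict filter, 122 and 730 over all retained cells, and 56 and 418 with DESeq2. The smaller UMI total of the deficient library does not account for the excess, since the ratio was 3.14 with all 3 sums thinned to 1 total. Transcript GC content had Spearman's rho of -0.017 with log2 fold change across genes (bootstrap 95% interval -0.034 to 0.0015). That argues against a GC trend over all tested genes, which are not independent replicates. Most of these genes were not called, and the GC content of the called lower genes was not compared with that of the others. The value therefore cannot tell whether GC content plays a part in the lower calls. A shift of the whole library remains open: in cells of the other named classes, 244 measurable called lower genes had a median log2 ratio of -0.57 (-0.72 to -0.48), an interval that holds the bound of -0.49 set for it. All measurable genes had a median of 0.12 in those cells; taken against it the called genes lie lower still, toward a shift, but the bound was set beforehand without it. The pooled classes also differ in make-up, with 295 and 143 neutrophil-like cells in WT and 19 in the deficient library. The few deficient cells of those classes limit that value, and the genotype remains an open explanation, confounded with the single library.

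Ccr6, Tagap1, Rnaset2b and Dynlt1c lie between 5 and 10 Mb on chromosome 17, which carries the classical MHC class II genes between 30 and 35 Mb, so a donor strain haplotype kept beside the targeted locus may contribute. The called members of the MHC lists, H2-Oa (start 34092340), H2-T23 (36029773) and H2-T22 (36037128), lie on this chromosome too, so the same may hold for them. The first look was at bins of 5 Mb, of which the bin from 5 to 10 Mb had 10 of 29 genes called, the highest share of the 226 bins with at least 20 tested genes. UMIs can be split between near-identical copies there: without Rnaset2a, Rnaset2b, Tagap and Tagap1 it was 6 of 25, and without the Dynlt1 copies as well 5 of 22, still ranked 1. On the same chromosome, 3 of 21 were called from 15 to 20 Mb, 0 of 72 from 20 to 25, 9 of 90 from 25 to 30, 6 of 92 in the bin of the class II genes and 11 of 70 from 35 to 40. Over the wider window, 4282744 to 64282744, the gathering did not hold for calls of both directions together. There 52 of 522 genes were called against 921 of 11173 elsewhere, an odds ratio of 1.23 (95% interval 0.899 to 1.66). By direction, 21 were higher and 31 lower in the window, against 179 and 742 elsewhere. By share of higher genes, the bins from 5 to 10 Mb (13.8%) and 35 to 40 Mb (8.57%) ranked 2 and 3 of the 226. The split by direction was not tested, so a gathering of the higher calls remains open. The haplotype itself was not decided, since 68.8% of 16 measurable called window genes (41.3 to 88.98) had the same sign in the other classes, against 81.4% of 279 elsewhere.

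Neutrophil markers were lower in deficient microglia, with 9 of 13 called. Free RNA from neutrophils is a candidate source: their median log2 fold change was -4.05 (bootstrap 95% interval -4.28 to -3.15), and the log2 ratio of the neutrophil share of UMIs between genotypes was -3.06. That lies only just inside the limit of 1 for a match, a limit written after lower neutrophil genes had been seen, and the bootstrap interval leaves the ratio just outside, so the match is weak. Neutrophil-like cells held 8.49% and 4.32% of UMIs in the WT libraries and 0.768% in the deficient library.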
